A study of Arabidopsis thaliana with 12 samples.

How the data were processed

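The 12 samples are 6 H2O and 6 pStau arrays of wild-type Arabidopsis thaliana total RNA, grouped by their titles in the labels. The values are array intensity values as the authors deposited them, in 1 table for the whole series, and were taken to be linear, since their unit is not stated. How the authors corrected background, scaled or centred the values is not given in the sources used here, nor are the dyes or the scanner, so the scaling and centring stay unknown. Per array, 11.5% to 17.3% of values were exactly 0, the medians were 0.405 to 0.485 for H2O and 0.169 to 0.392 for pStau, and the totals were 3054 to 3562. The highest value was 100, which 3 probes reached, on 10 of the 12 arrays, so 100 was taken as a ceiling. The number of arrays limits the precision.

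Probes were named through the platform annotation, which can be old, and updated through the RefSeq gene table of the assembly TAIR10.1, used for names alone. Of 3439 probes, 692 had 1 gene, 870 several and 1877 none. Of the 692, 690 matched that table and 2 kept the annotation's name. No gene was named from a probe with several.

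The design fixed before the data were examined used the table as deposited if the array medians agreed within 10%, and quantile normalization otherwise. The highest and lowest medians differed 2.87-fold, so the arrays were quantile normalized. This was applied to positive values, since ranking the zeros gave probes at 0 on every array different values between groups. Zeros and values below the 1st percentile of the normalized positive values were then set to that percentile, 0.0169, as 1 floor for all arrays in place of a floor per array, before log2 was taken. The 183 probes at 0 on all 12 arrays have no variance and were left out, so 3256 were tested. These refinements were made after seeing the data. Fold differences are on this floored scale.

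Group means were compared with lmFit and eBayes in limma 3.58.1 under R 4.3.3, two-sided, without a block, with Benjamini-Hochberg adjustment over the probes tested and an adjusted p threshold of 0.05. Gene lists with at least 3 measured genes were tested with camera and its preset correlation of 0.01. The naming rule took, among probes with 1 gene past the threshold whose 6 pStau arrays all lay on the same side of the H2O mean, the 12 largest rises and the 12 largest falls, and up to 4 members of each list with the smallest unadjusted p. This named 40 genes, of which 34 passed. RPL29 and RPS10 were named beyond the rule to complete their list, and genes of the closing section's added lists were chosen after gene names were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

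The replicate number in the titles may pair an H2O array with a pStau array. Deviations from the group mean correlated between arrays of the same number with r from 0.31 to 0.54 in all 6 numbers, over the stated minimum of 0.1, and each H2O array correlated best with the pStau array of its own number, so the numbers were taken to pair the samples. The source of that pairing is not stated in the labels. With the replicate block 1279 probes passed, 600 higher and 679 lower.

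The fit was tested on simulated data with the means and SDs of the 3256 probes for pStau vs H2O and 200 changed probes. It recovered 55% of 100 probes changed 2-fold and 27% of 100 changed 1.5-fold, with 2 false calls among 84. With 3 samples per group each measured on 2 arrays and no difference simulated, the fit to 12 arrays gave 63 calls among 3256 probes, and fits that averaged the paired arrays or used them as a random block gave 0. The averaged fit, with or without the array set as a block, recovered 0% of the probes changed 2-fold or 1.5-fold in such data. In 50 simulated draws, camera passed 100% of lists of 6 genes raised 2-fold and 4% of unchanged lists. Those draws had independent genes and arrays, changed no gene outside the list and counted an unadjusted p under 0.05. The estimated correlation of the real ribosomal list was 0.18 and consecutive arrays were alike, so these shares need not hold for the real lists.

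Alternatives covered other normalizations, low-value rules, spread estimates, tests and thresholds, the replicate block, other list tests and leaving out arrays. The table as deposited, arrays scaled to the same total, arrays centred on their median and cyclic loess used a floor per array. Averaging consecutive arrays, using them as a random block, ranking zeros, cyclic loess, leaving out probes with zeros and leaving out array sets were added after seeing the data. Other microarray files, such as scanner output, were not used here.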

Results

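Transcript levels were measured on 12 arrays with total RNA from wild-type Arabidopsis thaliana of the Columbia 0 ecotype. The labels compare plants kept in water for 8 h, called H2O here, with plants that had 4 h of water and then 4 h with staurosporine, called pStau here, with 6 arrays in each group. Staurosporine is an inhibitor of many protein kinases. Its dose is 25 mM at pH 5.5 in the labels, and the unit of that dose was not checked against any other source. Each array gave an intensity for 3439 probes, with values between 0 and 100 that were taken as linear. Of these probes, 692 are paired with 1 gene, 870 with several genes and 1877 with none, so the genes named here cover only part of the array. The labels do not say that the arrays of a group came from separate plants, so p-values measure only the spread between these samples, which may be technical.

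**Figure D1:**
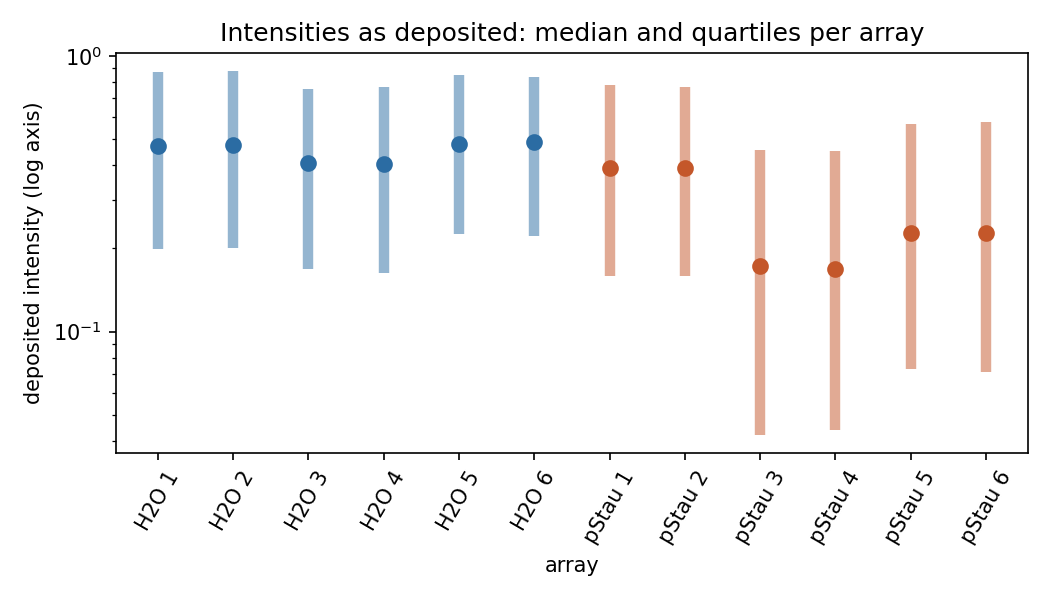
Median (point) and lower to upper quartile (bar) of the deposited intensity on each of the 12 arrays, on a log axis, with H2O arrays in blue and pStau arrays in orange. The 6 H2O medians lie between 0.405 and 0.485, pStau arrays 1 and 2 lie at 0.392, and pStau arrays 3 to 6 lie between 0.169 and 0.228.

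The comparison of pStau with H2O asks which transcripts differ after the staurosporine treatment. PSAN, a subunit of photosystem I, was 3.90-fold lower in pStau (log2 change -1.97 ± 0.13, SE, n = 6 per group, limma adjusted p = 5.89e-06) and lay below the H2O mean on all 6 pStau arrays. Here and below, n = 6 per group counts each array as a separate sample. For PSAN the limma adjusted p was 0.000216 with consecutive arrays as a random block and 0.000663 with the replicate number as a block. It was 0.151 with consecutive arrays averaged and the array set as a block. PSBW, a small subunit of photosystem II and a very bright probe, was 1.33-fold higher (log2 change 0.42 ± 0.06, SE, n = 6 per group, limma adjusted p = 0.000636). The log2 change of PSBW was 0.90 as deposited, 1.77 with arrays centred on their median and 0.13, not passing, with cyclic loess. The largest rise among genes passing the naming rule was that of AT4G02580, the 24 kDa subunit of mitochondrial complex I, at 4.57-fold (log2 change 2.19 ± 0.39, SE, n = 6 per group, limma adjusted p = 0.00201). AT4G02580 was listed at 0 on 1 H2O array, so the size and rank of its rise depend on the floor. With a floor at the 5th percentile its log2 change was 1.58, below the 1.76 of AT3G61870. With zeros ranked it was 1.65, below the 1.83 of AT3G61870. The probes of AT4G02580, FATB and AT3G61870 are dim (H2O level percentiles 9.67, 13.4 and 13.6). With the dimmest 25% of probes left out, none of these rises was tested. The call of AT4G02580 ended with the table as deposited (log2 change 1.24, adjusted p = 0.0858) and with arrays scaled to the same total (1.23, adjusted p = 0.0835), which was 2.04 above the median change of all probes in both. Among the genes passing that rule, the largest fall that did not involve arrays at 0 was that of AT1G74070, a cyclophilin-type isomerase, at 4.29-fold (log2 change -2.10 ± 0.30, SE, n = 6 per group, limma adjusted p = 0.000721).

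Of 3256 probes tested, 536 were higher and 613 lower in pStau at an adjusted p under 0.05, together 1149 or 35.3%. At least 2-fold differences made up 150 of the higher and 268 of the lower probes. Among the 652 tested probes with 1 gene, 95 were higher and 145 lower. The split depended on scaling: it was 183 higher and 1519 lower with the table as deposited, 180 and 1628 with arrays scaled to the same total, and 915 and 487 with arrays centred on their median. As deposited, the median change over all probes was -0.80 on the log2 scale, and -0.82 after scaling to the same total.

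Arrays with consecutive numbers in a group (1 and 2, 3 and 4, 5 and 6) resembled each other more closely than other arrays of the group. Averaging each such pair, an alternative chosen after seeing the data, left 3 values per group and 3 probes past the threshold, 1 higher and 2 lower, none of them paired with a single gene. With the array set also as a block, limma called 0 probes and the smallest adjusted p was 0.151. In that fit 870 of 3256 probes had an unadjusted p under 0.05, where chance gives 1 in 20, although probes are not independent. In simulated data with 200 changed probes and no pairing between groups, both averaged fits recovered 0% of probes changed 2-fold or 1.5-fold. The real data may hold more changed probes and its numbers were paired, so this recovery need not hold there. The low counts alone cannot tell whether the groups differ. Treated as a random block, the same pairs left 524 probes, 260 higher and 264 lower, and 20 of the 34 named genes that passed. This ended the calls of FATB, AT3G57570, DI21, AT5G27560, AT2G21530, DRT101, AT1G13970, AT2G27630, APS4, PSBY, AT3G54210, AT4G01310, AT2G23070 and CHLM. Without arrays 3 and 4 of both groups 488 probes and 15 of those 34 genes passed, and without arrays 5 and 6 of both groups 507 probes and 16 of them. Leaving out arrays 1 and 2 of both groups instead gave 1351 probes, 613 higher and 738 lower, and 31 of those 34 genes. The calls of 10 named genes held in the random block fit and without each of the 3 array sets, namely PSAN, PSBW, AT4G02580, AT1G74070, AT3G20150, AT3G61870, AT2G15440, AT3G07790, FBL17 and AT5G63390. Of these, AT4G02580, AT3G61870 and AT5G63390 are dim probes, which were not tested with the dimmest 25% of probes left out.

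AT3G20150, a kinesin motor protein, rose 2.23-fold (log2 change 1.16 ± 0.10, SE, n = 6 per group, limma adjusted p = 2.98e-05). FATB, the plastid thioesterase that releases saturated fatty acids from acyl carrier protein, rose 3.77-fold (limma adjusted p = 0.0235, n = 6 per group), and leaving out pStau array 3 or pStau array 5 ended its call, with an adjusted p of up to 0.0524. FATB lay at the floor on H2O array 4. Its log2 change of 1.91 was 1.57 with a floor at the 5th percentile and 1.66 with zeros ranked. AT4G01810, a protein of the Sec23/Sec24 family of vesicle coats, rose 2.53-fold. FBL17, an F-box protein that acts in the cell cycle, rose 2.11-fold. AT4G15840, a BTB/POZ protein, rose 2.31-fold and AT3G57570, an ARM repeat protein, rose 2.38-fold. DI21, a drought-induced gene, rose 2.29-fold (limma adjusted p = 0.0223, n = 6 per group), with a log2 change of -0.19 between arrays 1 and 2 of the groups, 1.69 between arrays 3 and 4 and 2.08 between arrays 5 and 6, and with the replicate number as a block its adjusted p was 0.0574. AT3G61870, AT2G15440, AT3G07790 and AT5G27560 rose by log2 changes of 1.79, 1.27, 1.22 and 1.19. As deposited, the calls of FATB (1.17), FBL17 (0.38), AT4G15840 (0.43), AT3G57570 (0.83) and AT5G27560 (0.11) ended. With arrays scaled to the same total those of FATB (1.16), FBL17 (0.37), AT3G57570 (0.82) and AT5G27560 (0.099) did. Relative to the median change of all probes, FATB, FBL17, AT4G15840, AT3G57570 and AT5G27560 were at 1.97, 1.19, 1.23, 1.64 and 0.92 with both of these scalings.

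Most of the genes with the largest falls were listed at 0 on some pStau arrays, where their levels were set to a floor, so the sizes of those falls depend on that floor. AT4G05070 (log2 change -3.75), AT2G46910, of the plastid fibrillin family (-3.32), AT4G37420 (-3.23) and AT2G21530, an FHA domain protein (-2.91), were each listed at 0 on 4 of 6 pStau arrays and on 0 H2O arrays. For AT4G05070, AT2G46910 and AT4G37420 these were pStau arrays 3 to 6. Those arrays had the lowest medians and the most zeros, 13.7% to 17.3% of values against 11.5% to 13.1% on H2O arrays. The normalization left zeros at the floor, so a lower signal of the whole array was not told apart from a fall of these genes. Between arrays 1 and 2 of the groups, the log2 changes of AT4G05070, AT2G46910 and AT4G37420 were -0.94, -1.46 and -0.85. Their calls ended without arrays 3 and 4 of both groups (limma adjusted p = 0.103, 0.0641 and 0.107). They also ended without arrays 5 and 6 (0.112, 0.106 and 0.104), but held without arrays 1 and 2. AT5G63390, of the O-fucosyltransferase family, fell by 2.27 on the log2 scale and was listed at 0 on 5 pStau arrays. AT1G13970 (-2.58) was at 0 on 3 pStau arrays, AT1G11820, a glycosyl hydrolase (-2.56), and AT2G27630 (-1.86) on 2, and DRT101, a DNA damage toleration gene (-2.80), and AT5G25990 (-2.13) on 1. With zeros ranked in the normalization, the falls of AT4G05070, AT2G46910 and AT4G37420 were -2.40, -1.97 and -1.87, and that of AT5G63390 was -0.59. The call of AT2G27630 (limma adjusted p = 0.0380, n = 6 per group) ended when any 1 of 9 single arrays was left out, with an adjusted p of up to 0.0738.

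**Figure D2:**
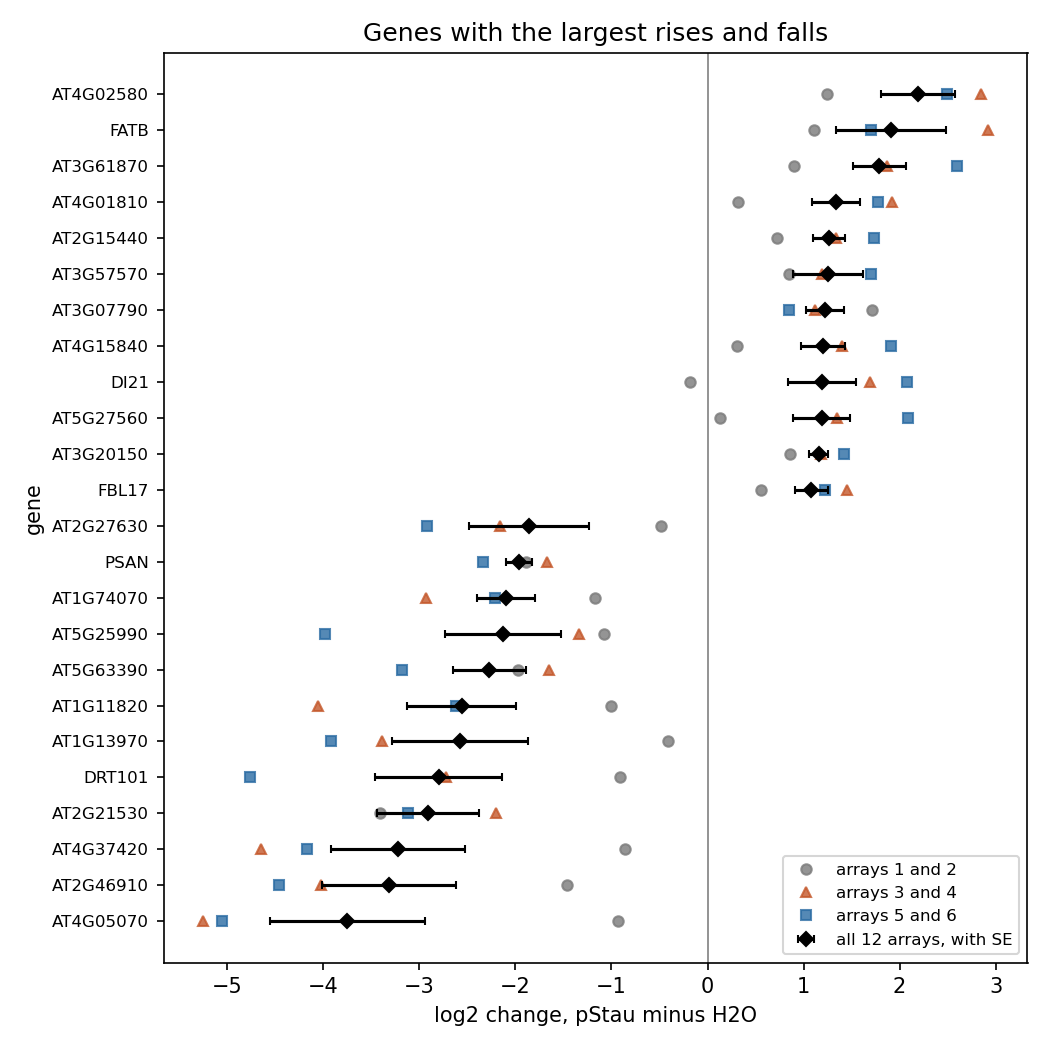
Log2 change, pStau minus H2O, of the 24 genes with the largest rises and falls under the naming rule. Diamonds show the change over all 12 arrays with its SE, and the other symbols show the change between arrays 1 and 2, arrays 3 and 4, and arrays 5 and 6 of the groups. PSAN lies at -1.89, -1.67 and -2.33 in these array sets, and DI21 is the gene with a set on the other side of 0, at -0.19. The falls of AT4G05070, AT2G46910 and AT4G37420 are smallest between arrays 1 and 2, at -0.94, -1.46 and -0.85.

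Gene groups were followed through 23 lists of mostly plastid functions, holding 464 genes, of which 21 were on the array under a single gene name and 20 could be tested. Of those 20, 4 rose, 8 fell and 8 did not pass, and 12 passed when adjusted over the list alone, as 1 list of the 20 genes. The light-harvesting list had 1 measured member, LHB1B2, a chlorophyll a/b-binding protein of photosystem II (LHCB1.5 in the list), which fell by 0.84 on the log2 scale (limma adjusted p = 0.00807, n = 6 per group). Its log2 changes in the 3 array sets were -1.46, -0.68 and -0.38. The call of LHB1B2 ended without arrays 1 and 2 of both groups (limma adjusted p = 0.0949) and without arrays 3 and 4 (0.0501). It held without arrays 5 and 6 (0.0133). In the photosystem II list, PSBW rose, PSBY fell by 0.51 (limma adjusted p = 0.00790, n = 6 per group) and PSB27 did not pass (log2 change 0.12 ± 0.28, SE), but passed at 0.86 with arrays centred on their median (adjusted p = 0.0146). The changes of LHB1B2 and PSBY were 0.074 and 0.071, not passing, with arrays centred on their median, and as deposited they lay 0.012 and 0.0090 above the median change of all probes. PSAN was the measured member of the photosystem I list, and its change as deposited was -2.36, which is -1.56 relative to that median. LHB1B2, PSBY, PSB27 and PSAN are bright probes (H2O level percentiles 94.5, 86.5, 88.0 and 92.8). Brighter probes had higher ratios as deposited, and centring arrays on their median leaves this in place. The median change of all probes is therefore a rough yardstick for them, and values near it do not show a lack of change.

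Among genes of pigment, redox and sulfur metabolism, CHLM, the methyltransferase of chlorophyll synthesis, fell by 0.74 on the log2 scale (limma adjusted p = 0.00405, n = 6 per group). The call of CHLM ended with consecutive arrays as a random block (adjusted p = 0.0566) and without arrays 5 and 6 of both groups (0.0612). AT3G52960, the peroxiredoxin PRXIIE of the antioxidant list, fell by 1.24 (limma adjusted p = 0.0235, n = 6 per group), with log2 changes of -0.18, -2.22 and -1.32 in the 3 array sets. Its call ended without number 3, 4, 5 or 6 (adjusted p up to 0.0817), without arrays 3 and 4 (0.0891) and without arrays 5 and 6 (0.195). APS4, an ATP sulfurylase, rose by a log2 change of 0.49 (limma adjusted p = 0.0178, n = 6 per group), but its change was -0.20 as deposited and -0.22 with arrays scaled to the same total, which was 0.60 above the median change of all probes. AT2G23070, a catalytic subunit of the protein kinase CK2 (CKA4 in the list), was the measured kinase and rose by 0.29 (limma adjusted p = 0.0376, n = 6 per group). That gene's adjusted p was 0.0686 with the replicate number as a block, and leaving out any 1 of 7 single arrays ended the call. Its change was -0.40 as deposited and -0.41 with arrays scaled to the same total, which was 0.40 above the median change of all probes. Its call also ended with cyclic loess (log2 change 0.37, adjusted p = 0.0552), a pseudocount, an intensity trend with a robust fit, or the exact rank sum test. The thioredoxin list held AT2G04700, or FTRB (0.62 ± 0.47, SE), and NTRC (0.02 ± 0.20, SE), neither of which passed, and the Calvin-Benson list held PRK (0.19 ± 0.17, SE), which did not pass. In the lipid list, FATB rose and AT1G24360, or KAR, did not pass (0.13 ± 0.12, SE), but passed at 0.81 with arrays centred on their median (adjusted p = 0.00257). KAR is a bright probe too (H2O level percentile 85.5), so the same limit holds for that value.

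Of 6 measured plastid ribosomal proteins, 3 fell and 3 did not pass. AT3G54210 (RPL17) fell by 0.45 on the log2 scale, with an adjusted p of 0.0207 in limma, 0.0535 with the replicate number as a block and 0.244 with arrays centred on their median, where the change was -0.25. AT4G01310 (RPL5) fell by 0.44 (limma adjusted p = 0.0425), and its call ended when any 1 of 10 single arrays was left out, with an adjusted p of up to 0.0886. It also ended with arrays centred on their median (log2 change -0.44, adjusted p = 0.0603), zeros ranked (-0.38), cyclic loess (-0.44), a pseudocount, a fit without variance moderation or the exact rank sum test. AT1G29070 (RPL34) was listed at 0 on all 6 pStau arrays and on 1 H2O array (limma adjusted p = 0.00683), so no fold is given. Its call ended with zeros ranked (adjusted p = 0.103). AT5G65220 (RPL29), AT3G13120 (RPS10) and AT1G64510 (RPS6) did not pass, and the last was listed at 0 on 5 H2O and 4 pStau arrays. As a group the ribosomal list had a mean log2 change of -0.47 (camera adjusted p = 0.316, and adjusted p = 0.635 with an estimated correlation). That mean rests in part on RPL34 at the floor, and was -0.24 with a floor at the 5th percentile, -0.19 with zeros ranked and -0.28 over the 4 members above 0 on every array. The 3 photosystem II genes had a mean of 0.0068 (camera adjusted p = 0.665), and of 0.90 with arrays centred on their median (camera adjusted p = 0.139). Thus 0 of the 2 lists with at least 3 genes passed in camera, with 0 at an unadjusted p under 0.05. Camera compares a list with the other genes, while fry tests it against no change. Fry passed the ribosomal list (adjusted p = 0.0405). Since 35.3% of the probes tested were called, a pass in fry does not show a shift particular to a list. No gene of 12 lists was tested, among them both lists of markers of other cell types and the housekeeping list.

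**Figure D3:**
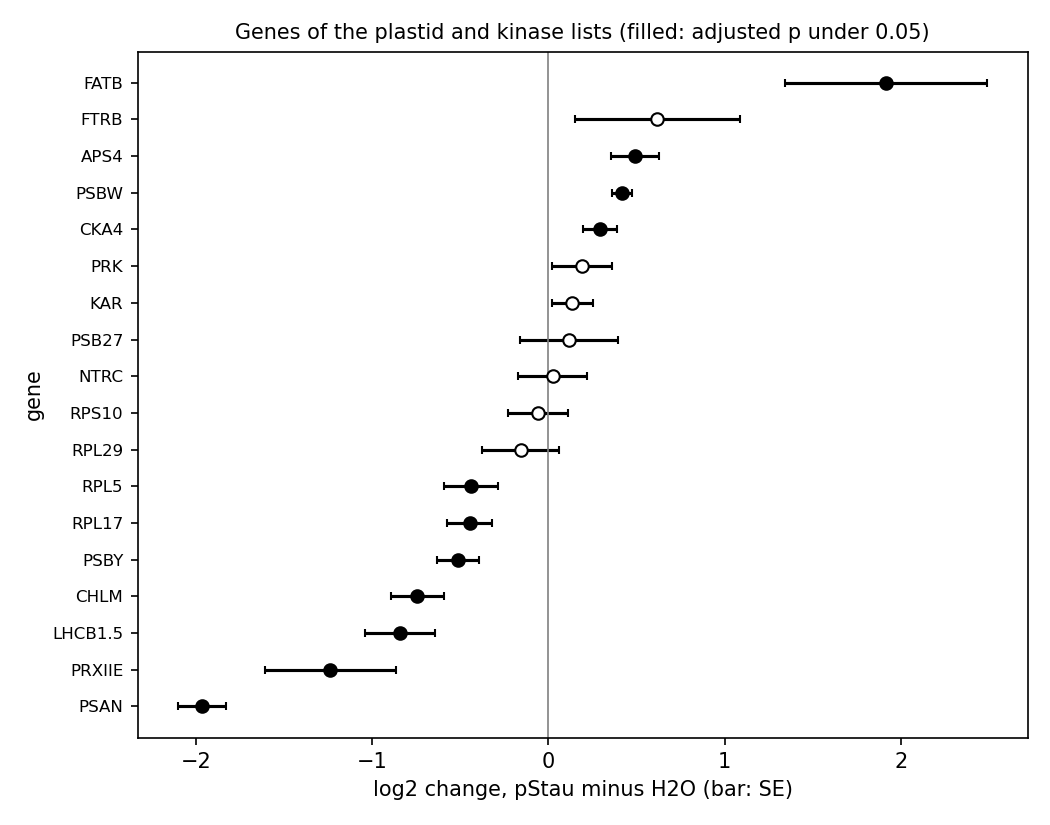
Log2 change, pStau minus H2O, with its SE over 12 arrays, for 18 tested genes of the fixed lists, leaving out RPL34 and RPS6, which were mostly listed at 0. Filled points passed an adjusted p under 0.05. The changes of APS4 and CKA4 turn negative with the table as deposited and with arrays scaled to the same total, where they lie 0.60 and 0.40 above the median change of all probes, and those of LHCB1.5 and PSBY turn to 0.074 and 0.071 with arrays centred on their median. LHCB1.5 and PSBY are bright probes, and brighter probes had higher ratios as deposited.

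Across the tested probes, log2 changes in the array sets 1 and 2, 3 and 4, and 5 and 6 were compared, each set having its own H2O arrays. Pearson's r across probes was 0.46 between the first set and the second, 0.47 between the first and the third, and 0.73 between the second and the third, although probes are not independent replicates. The spread of changes (SD) was 0.59 in arrays 1 and 2, 1.04 in arrays 3 and 4 and 1.11 in arrays 5 and 6. Changes had the same sign in all 3 sets for 52.5% of probes, against 21.2% expected from independent sets with the same shares of rises and falls. As deposited, the log2 ratio of the brightest probes exceeded that of middling ones by 0.32, 1.52 and 1.56 in these sets. A difference in detection shared by pStau arrays may also give the same signs, so this agreement does not separate it from the treatment.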

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

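In this part, the comparison with other splits of the arrays was written before its result was seen, and the look at consecutive arrays and the tests on the deposited intensities were chosen after the data were seen.

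In H2O, AT2G46910 had a log2 level of -2.62 on array 3, against -1.56 on the next array, a gap of 0.664 of the group's range. PSB27 had a log2 level of 1.48 on H2O array 5, against 0.31 on the next array. AT5G63390 had a log2 level of -4.30 on pStau array 2, while the other 5 pStau arrays lay at the floor of -5.88. AT1G64510 had a log2 level of -5.40 on pStau array 4, against -5.72 on the next array and -5.88 at the floor. These 4 samples stood far from the others of their group among 88 groups looked at. Chance gives 1 in 20, or 4.4, if the 6 values are independent and normally spread. Consecutive arrays were alike and some groups were tied at the floor, so 4.4 is only a rough guide. For AT5G63390, the 5 equal values at the floor make any other value stand out.

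The first pattern is the number of probes past the threshold, 1149. Among 100 of the 462 possible splits of the 12 arrays, 1 gave as many, the real one, and the highest of the others gave 240. Among the 32 splits that part all 6 number pairs, 1 gave as many, and the highest of the others gave 0. Both comparisons take each array as a separate sample, which the likeness of consecutive arrays described next speaks against. Of the 32 splits, 4 keep consecutive arrays together, too few for a share under 0.05, so a chance division cannot be told apart from a group difference by this count.

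The second pattern is the likeness of consecutive arrays within a group. Each of the 6 consecutive pairs was closer than any other pair of its group. Correlations of deviations from the group mean were 0.18 to 0.73 for these pairs of H2O arrays and 0.011 to 0.62 for those of pStau arrays, against -0.43 to -0.25 and -0.38 to -0.28 for other pairs. Repeat measurement of 1 sample and a shared growth or hybridisation batch both stay open, since the labels name neither, and no explanation of this pattern was tested.

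The third pattern is that, as deposited, most probes were lower and the brightest were higher on pStau arrays 3 to 6 than on the matching H2O arrays. With 1 scale factor per array, bright and middling probes would share a ratio. Over 5 bins of brightness, the log2 ratio of the brightest 5% exceeded that of the third bin by 1.52 (95% bootstrap interval 1.38 to 1.66) in arrays 3 and 4 and by 1.56 (1.39 to 1.74) in arrays 5 and 6. A scale factor with a background offset, set from the brightest bin and the second, predicted a level in the third bin 1.68 times (1.55 to 1.84) and 1.69 times (1.53 to 1.84) the observed one. All these intervals resample probes within fixed arrays, so they do not measure the spread between arrays or samples. An effect of the treatment on most transcripts and a non-linear difference in detection stay open; neither was tested, since no external controls were used here. The median change as deposited was -0.24 in arrays 1 and 2, against -1.09 and -0.97 in the other sets.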

How the results depend on the processing

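The settings that average or block consecutive arrays, rank zeros, use cyclic loess, leave out probes with zeros or leave out array sets were chosen after seeing the data; the causes of the differences were not tested unless stated. Against 1149 probes and 34 passing named genes, 1808 probes passed with arrays scaled to the same total, 584 probes and 22 genes at an adjusted p under 0.01, 3 probes and 0 genes with consecutive arrays averaged, and 0 probes and 0 genes with the replicate block by set added, where fewer values enter. Consecutive arrays as a random block left 524 probes and 20 genes, leaving out arrays 3 and 4 left 488 and 15, and leaving out arrays 5 and 6 left 507 and 16. Leaving out arrays 1 and 2 gave 1351 probes and 31 genes. Leaving out probes at 0 on any array left 21 named genes, since it tests fewer. Without the dimmest 25% of probes, 1032 probes and 25 named genes passed. That setting ended the call of AT2G23070 (adjusted p = 0.0543). It did not test 8 other called genes (AT4G02580, FATB, AT3G61870, AT5G27560, AT2G21530, AT5G63390, AT2G27630 and AT1G29070). Leaving out 1 array or 1 number gave 744 to 1248 probes, the lowest without number 5, and 24 to 34 named genes. With the replicate block, 1279 probes passed, and the calls of DI21, AT3G54210 and AT2G23070 ended; it changed no other call of a named gene or list. Leaving out 1 array ended the call of 4 named genes, and leaving out 1 number that of 11 (FATB, AT3G57570, DI21, AT1G13970, AT5G25990, AT2G27630, AT3G52960, APS4, AT3G54210, AT4G01310 and AT2G23070). Fry, which tests a list against no change and not against the other genes, passed 1 list against 0. As deposited and with arrays scaled to the same total, changes turned to -0.38 and -0.39 for PRK, -0.20 and -0.22 for APS4, -0.00636 and -0.020 for PSB27, -0.055 and -0.069 for AT1G24360, -1.58 and -1.59 for AT1G64510, -0.40 and -0.41 for AT2G23070, -0.67 and -0.68 for AT2G04700, and -0.71 and -0.72 for NTRC. Both scalings moved all probes, and relative to the median change of all probes (-0.80 and -0.82) these 8 genes lay at 0.097 (NTRC) to 0.80 (PSB27), except AT1G64510 at -0.77. Brighter probes had higher ratios as deposited, so for a bright gene such as PSB27 (H2O level percentile 88.0) this median is a rough yardstick. As deposited 29 named genes passed, and of the 34 called, 7 calls ended, that of AT2G23070 turned, and AT1G64510 and NTRC passed as falls. With arrays scaled to the same total 30 passed, 6 calls ended and the same 3 genes passed as falls. These scalings, and centring on the median, used a floor per array. AT1G64510 was listed at 0 on 5 H2O and 4 pStau arrays, so its falls with them rest on those floors. With arrays centred on their median 32 passed, the calls of LHB1B2, PSBY, AT3G54210 and AT4G01310 ended, PSB27 (0.86) and AT1G24360 (0.81) passed, and changes were 0.074 for LHB1B2, 0.071 for PSBY and -0.71 for AT1G64510. NTRC, which did not pass, was at -0.000789 with array weights, -0.15 without arrays 1 and 2, -0.093 without arrays 3 and 4, and -0.097 to 0.15 with 1 array or number left out. PSB27 was at -0.18 without arrays 1 and 2 and at -0.049 to 0.36 with 1 array or number left out. AT1G24360 was at -0.092 without arrays 1 and 2, and PRK at -0.00736 without arrays 5 and 6. The photosystem II list had a mean of -0.095 with cyclic loess and 0.90 with arrays centred on their median. Values at 0 limit what can be said of dim probes.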

Other observations

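The lists described here were put together after gene names were seen, and their tests were chosen after seeing the data. Of 4 measured members of the glycosyl hydrolase 9B family, whose enzymes act on cell wall glucans, all 4 fell: GH9B16 by a log2 change of -0.68 (limma adjusted p = 0.00573), GH9B11 by -0.61, GH9B12 by -0.53, and GH9B8, which was listed at 0 on all 6 pStau arrays. The call of GH9B11 ended with the replicate number as a block (adjusted p = 0.113), with arrays centred on their median (log2 change -0.50, adjusted p = 0.0685) and with zeros ranked (-0.56, adjusted p = 0.0531), and that of GH9B8 with zeros ranked (adjusted p = 0.258). The mean change of the 4 was -0.82 (camera adjusted p = 0.0873, and adjusted p = 0.242 with an estimated correlation), so the family did not pass in camera. That mean rests in part on GH9B8 at the floor, and was -0.51 with a floor at the 5th percentile and -0.47 with zeros ranked. The list passed in camera with cyclic loess (adjusted p = 0.0371) or a pseudocount (0.0487). It also passed in fry (adjusted p = 0.000679), which does not compare it with the other genes. Of 8 genes for photosystem and cytochrome b6f subunits and their assembly factors, 5 fell, 1 rose and 2 did not pass, with a mean log2 change of -0.57 (camera adjusted p = 0.0873, and adjusted p = 0.242 with an estimated correlation). That list passed in camera with cyclic loess (adjusted p = 0.0371), and in fry, without a comparison with the other genes (adjusted p = 7.77e-05). Besides those described, the falls were those of LPA19, a photosystem II assembly factor, at -0.77, and CCB3, which acts in cytochrome b6 maturation, at -0.84. With arrays centred on their median the mean of these 8 was -0.14, and the changes of LHB1B2 and PSBY were not below 0. Both are bright probes, and brighter probes had higher ratios as deposited.

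Z-ISO, an isomerase of carotenoid synthesis, fell by 1.61 on the log2 scale (limma adjusted p = 0.00244), and AT1G74470, the geranylgeranyl reductase CHLP, rose by a log2 change of 0.33 (limma adjusted p = 0.0186), which was 1.21 with arrays centred on their median. Its call ended as deposited (log2 change 0.34, adjusted p = 0.0647) and with arrays scaled to the same total (0.33, adjusted p = 0.0599), which was 1.14 above the median change of all probes in both. It is a bright probe (H2O level percentile 89.1), and brighter probes had higher ratios as deposited. GLX2-1 fell by 1.66 (limma adjusted p = 0.0420), a call that ended with cyclic loess (log2 change -1.76, adjusted p = 0.0683). CRR21 and PAC, both needed for plastid RNA processing, rose by log2 changes of 0.51 and 0.61, but both calls ended as deposited (-0.13 and 0.067) and with arrays scaled to the same total (-0.14 and 0.053), where they lay 0.68 and 0.87 above the median change of all probes. AT5G55580, the organelle transcription factor mTERF9, fell by 0.80, a call that ended with arrays centred on their median (-0.68, adjusted p = 0.0690). With consecutive arrays as a random block the calls of GH9B8, GH9B11, GH9B12, LPA19, AT1G74470, GLX2-1, CRR21 and AT5G55580 ended, with adjusted p from 0.0824 to 0.240. The 5 other added lists had camera adjusted p from 0.539 to 0.798.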
